A study of Homo sapiens with 9 samples.

How the data were processed

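H3K27ac, an acetylated form of histone H3 found at active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in HEC1B, an established human endometrial cancer cell line. There were 9 libraries, 1 for each of the siRNAs siNC, siPRMT6-1 and siPRMT6-2 at 24, 36 and 48 h. The labels do not say that the times were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries are named by siRNA and hour. Where a library is left out, replicates 1, 2 and 3 of a siRNA are its 24, 36 and 48 h libraries. The names of the deposited files carry a date-like code. The 3 libraries of 24 h shared 1 code, as did the 3 libraries of 48 h, whereas at 36 h the siNC library had another code than both PRMT6 siRNA libraries.

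Reads were aligned and summits called by the authors. The submitters' processing notes name Bowtie2 2.4.2, Picard 2.25.3, bedtools 2.30.0, MACS2 2.2.7.1 and the hg38 build, without their settings. Each deposited list held 1 library's summits, called per library and not on pooled libraries, with a position and a score. The score deposited by the authors is the −log10 of a q-value, inferred from the MACS2 format and from lowest values between 1.30 and 1.34 in every list, near the −log10 of 0.05. Sequencing depth, peak widths, an input control and caller settings were not used here, so the depth is unknown. A score of this kind grows with depth. Scores were therefore not compared across libraries, and a promoter without a summit is one not called at the depth of its library, not one without acetylation.

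Gene records came from RefSeq on GRCh38.p14, the assembly to which hg38 coordinates refer. The plan, fixed before the data were examined, was a window around the start of the canonical transcript. The reference used here gives neither strand nor transcripts. The window was instead centred on whichever end of the gene record had a summit within 1 kb in more of the 9 libraries, with ties broken by the mean score and then by the nearest summit of any library. This choice was blind to the siRNA. A window called a promoter here can still lie at the far end of a gene or at a minor transcript start. Genes on chromosome Y, in mitochondria or without a chromosome were left out. Of the 19974 protein-coding genes kept, 8505 had a summit at 1 end in all 9 libraries and at the other end in none. A promoter was called in a library when a summit lay within 1 kb. Summits of all libraries were extended by 250 bp and merged into 74927 regions, of which the 58808 more than 2.5 kb from every window centre are called distal. Distal regions can therefore include transcript starts inside a gene or at its other end. Neighbouring genes with windows over the same summits carry the same values and are named together.

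Gained means called in all 6 PRMT6 siRNA libraries and in no siNC library, and lost the reverse. Such counts were compared with all 84 splits of the libraries into 3 and 6. Single values were tested by an exact two-sided permutation test that moved the siNC label over the 3 libraries of each time, in 27 arrangements, with a smallest possible p of 0.037. For the 9818 promoters called in all 9 libraries, the highest score in the window was ranked within the library and turned into a normal score. The difference of normal scores is called the rank shift. It is a relative position among the same promoters in every library, in SD units of a normal distribution, and not a level of acetylation. Rank shifts were fitted with limma 3.58.1 in R 4.3.3, with time as a block and all libraries in the fit, and adjusted by Benjamini-Hochberg at 0.05. Every adjusted p of a promoter is from limma. Gene lists with at least 3 such promoters were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Presence counts were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

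The 18 gene lists, of 554 genes that all matched the reference, were fixed before the data were examined. They were the type I interferon response, antigen presentation and the interferon gamma response, nucleic acid sensing and interferon signalling, apoptosis, p53 targets, the cell cycle and DNA replication, cyclin-dependent kinase inhibitors, NF-kB and inflammation, the unfolded protein and integrated stress response, protein arginine methyltransferases, the histone acetylation and H3K4 methylation machinery, epithelial markers, mesenchymal markers, the endometrial and Mullerian lineage, Myc targets and ribosome biogenesis, housekeeping genes, leukocyte markers, and endothelial and fibroblast markers. The type I interferon and nucleic acid sensing lists share 7 genes. The rule for named genes took the arginine methyltransferases, the promoters with the largest rank shifts among those past the threshold (10 per direction for the pooled comparison, 5 for each siRNA and for the change over time), the promoters with the smallest p where too few passed, up to 4 members per list, and the gained and lost promoters and regions with the highest median percentile within their libraries. Some genes that the rule would name are not reported here. Genes and regions outside this rule are said to have been chosen after their values were seen.

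Libraries of the same time deviated together from the means of their siRNAs, with correlations across promoters of 0.0564 to 0.215, against −0.152 to 0.0522 for libraries of different times. The time block was part of the planned fit. The presence functions were tested on simulated lists over 6056 genes and recovered 91% of 100 planted gained promoters, 98% of 100 lost ones and 92% of 100 planted in siPRMT6-2 alone. All further genes with such a pattern lay within reach of a planted summit, which the simulation made certain. Every intended summit was present in these lists and none was added at random. The shares therefore check the code and not the sensitivity of the presence rules in real lists. The rank fit was tested on 9818 simulated promoters, 200 of them changed. For the pooled comparison it recovered 0% of changes of 0.5 on the log2 score scale, 12% of 1, 74% of 2 and 98% of 3. Here the change was planted alike in both PRMT6 siRNAs. These shares do not hold for a change in 1 siRNA alone, which adds to the residual spread of the pooled fit. For siPRMT6-2 against siNC, with the change planted in siPRMT6-2 alone, the fit recovered 0%, 6%, 58% and 84% of these sizes. Changes of 2 and 3 were added to the simulation after few or none of those of 0.5 and 1 had been recovered, so most promoter changes of the smaller sizes would not be detected with these libraries.

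Alternatives covered equal list lengths, a score of at least 5, other windows and overlaps, relaxed presence rules, other scalings of the scores, no time block, leaving out each library and leaving out the 36 h libraries. List tests for each siRNA, between the siRNAs and for the change with time were added after the data had been seen. So were counts for each PRMT6 siRNA alone and rank shifts of distal regions. Windows at either end of the gene record and 1 promoter per shared summit were also added then.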

Results

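HEC1B endometrial cancer cells carried siRNA against PRMT6, an arginine methyltransferase that modifies histone H3, or the siRNA labelled siNC, which served as the control. H3K27ac was profiled 24, 36 and 48 h later, per the labels, with 3 libraries per siRNA. The series title names interferon signalling and apoptosis, and the design asks which promoters and distal regions change their acetylation with PRMT6 knockdown, whether both siRNAs act alike, and whether the change grows with time.

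The PRMT6 promoter, at the gene on chromosome 1 from 107056674 to 107059294 (hg38), was called in all 9 libraries. Its summit score lay between the 78.1 and 88.6 percentile of its library. Its rank shift in knockdown was 0.13 ± 0.21 (SE, adjusted p = 0.953, limma). An siRNA acts on the mRNA, so this promoter does not measure the knockdown, and PRMT6 mRNA was not analysed here. The promoters of 8 of the 9 arginine methyltransferase genes were called in every library, and PRMT8 in none.

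The siNC libraries held 43191 ± 2780 summits (SD, n = 3), the siPRMT6-1 libraries 41968 ± 5180 (SD, n = 3) and the siPRMT6-2 libraries 45538 ± 4926 (SD, n = 3). Single lists ranged from 37890 to 51161. Knockdown libraries held 562 more than siNC at the same time, which was within the spread (p = 0.741, exact permutation). The difference was −352.5 at 24 h, 4400.5 at 36 h and −2361.5 at 48 h. Without siNC replicate 2 no difference can be taken at 36 h, and the mean over the other times was −1357. Between 10813 and 11363 of 19974 promoters were called per library. At the same time point, siPRMT6-1 and siPRMT6-2 shared 44.5% ± 2.85 of their summits (Jaccard index within 250 bp, SD over 3 pairs), siPRMT6-1 and siNC 46.4% ± 1.61, and siPRMT6-2 and siNC 45.5% ± 2.92. The difference between the knockdown pairs and the pairs with siNC was within the spread (p = 0.222, exact permutation).

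With both PRMT6 siRNAs pooled, no promoter was gained and 1 was lost. The lost call was at BAZ2A, which encodes a subunit of a nucleolar remodelling complex, on chromosome 12 from 56595596 to 56638318. Its window was centred on the lower end of the gene record, at 56595596. Without strand this end may not be the start of the gene, so the call may not concern the BAZ2A promoter. The median percentile of the summit in the siNC libraries was 13.9, and 7 libraries had a summit within 2.5 kb. Among distal regions, 19 were gained and 38 lost. The gained region with the highest percentile lay on chromosome 1 from 158002054 to 158002623 within KIRREL1, followed by chromosome 5 from 5025120 to 5026001, nearest to ADAMTS16, and chromosome 13 from 42133399 to 42134687 within DGKH. The highest lost regions lay on chromosome 4 from 131526553 to 131527494, nearest to PCDH10 at a distance of 1681583 bp, and on chromosome 1 from 112999044 to 112999696, nearest to SLC16A1. BAZ2A was in none of the 18 gene lists. Without the 36 h libraries, where siNC had another file code, 15 promoters were gained and 13 lost, and 124 distal regions were gained and 495 lost. Leaving out any 1 library gave 2 to 12 gained and 2 to 8 lost promoters. Gained distal regions then reached 114, without siNC replicate 1, and lost ones 261, without siNC replicate 2. Leaving out libraries loosens these rules by construction, so the higher counts do not show that the result depends on particular libraries.

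No promoter passed the threshold for a rank shift in the pooled comparison (limma, of 9818 promoters 315 higher and 314 lower at an unadjusted p under 0.05). The promoters with the smallest p, none of which passed, included SFN, an epithelial cell cycle regulator, at 1.07 ± 0.21 (SE), OSBPL7 at 1.24 ± 0.24 and the shared promoter of IFIT5 and LIPA at 2.24 ± 0.47 on the higher side. On the lower side were ODF2 at −1.17 ± 0.23 and TOB1 at −1.09 ± 0.23. These 5 had an adjusted p of 0.254. The type I interferon list had a median shift of 1.04 over 28 promoters, with HELZ2 at 1.64 ± 0.58 and PLSCR1 at 1.54 ± 0.60. Adjusted over the list alone, 9 of its promoters were higher and 0 lower. The antigen presentation list had a median of 0.61 over 18 promoters, 6 of them higher over the list alone, with APOL6 at 1.33 ± 0.47. The nucleic acid sensing list had a median of 0.22 over 20 promoters, 0 of them higher over the list alone. These 3 lists passed camera with the preset correlation (adjusted p = 1.27e-14, 7.94e-11 and 0.00135). None passed with an estimated correlation (adjusted p = 0.64, 0.64 and 0.753) or with fry (adjusted p = 0.642 each). The pooled fit has no term for the difference between the siRNAs, so that difference enters its residual spread. These tests are thus less able to pass for a change in 1 siRNA alone. The nucleic acid sensing list no longer passed without siNC replicate 2 (adjusted p = 0.14, limma's camera). The apoptosis list, the other theme of the title, had a median of 0.030 over 33 promoters, 0 of them higher over the list alone (adjusted p = 0.791), with CASP8, an initiator caspase, at 0.87 ± 0.25 (SE, adjusted p = 0.54).

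Each siRNA was next set against siNC by itself. In siPRMT6-2, the largest shift against siNC was at the promoter shared by IFIT5, an interferon-induced RNA-binding protein, and LIPA, on chromosome 10 where IFIT5 runs from 89414568 to 89420997, at 3.22 ± 0.24 (SE, adjusted p = 9.19e-07). HELZ2 rose by 2.87 ± 0.27, PLSCR1 by 2.86 ± 0.25, NMI by 2.80 ± 0.27, RIGI, a cytosolic RNA sensor, by 2.58 ± 0.27 and ISG15, a ubiquitin-like modifier, by 2.41 ± 0.25. Each of these was higher at all 3 times, as shifts chosen for their size in these same libraries make likely. Each passed under every alternative setting that tested it. ISG15 was chosen after its values were seen, as were the other list members named below for this siRNA. The ISG15 summit lay between the 61.4 and 64.7 percentile of the siNC libraries and between 96.8 and 98.4 in the siPRMT6-2 libraries.

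In all, 58 promoters at 50 distinct summit sites were higher in siPRMT6-2 than in siNC and 5 were lower. All 58 were higher at every time, which their selection on these same libraries makes likely, so this is no separate support. Of the 58, 27 belonged to the 3 interferon lists. Of the 28 type I interferon promoters tested, 19 rose over all promoters and 22 adjusted over the list alone, with a median shift of 1.76. They included EIF2AK2, the RNA-activated kinase PKR, at 2.09 ± 0.24, and the signalling factor STAT2, whose window is shared with APOF, at 1.69 ± 0.26. Of the 18 antigen presentation promoters, 7 rose and 13 adjusted over the list alone, with a median of 1.04. Among them were the shared promoter of the peptide transporter TAP1 and PSMB9 at 1.498 ± 0.25 and B2M at 1.31 ± 0.23. Of the 20 nucleic acid sensing promoters 3 rose, RIGI and STAT2 among them, and 5 adjusted over the list alone, with a median of 0.24. With an estimated correlation the adjusted p was 0.00626, 0.00485 and 0.0511 for these lists, and with fry 0.000714, 0.000714 and 0.00921. Of the 33 apoptosis promoters 1 rose, TNFSF10, which encodes the death ligand TRAIL and is itself interferon-inducible, at 1.59 ± 0.27 (SE, adjusted p = 0.00436). The apoptosis list as a whole did not pass camera (median 0.056, adjusted p = 0.339) or fry's test of a shift to 1 side (adjusted p = 0.167), but passed fry's test of change in either direction (adjusted p = 0.00015), which does not compare the list with other genes, and 2 of its promoters were higher adjusted over the list alone. The 5 lower promoters were NEK5 at −1.33 ± 0.29, TIAM1 at −1.21 ± 0.26, the pair TOM1L2 and DRC3 at −1.20 ± 0.24, and SHISA4 at −1.14 ± 0.23. Without the 36 h libraries 21 promoters passed, all of them higher and all among the 63. STAT2 did not (1.54, adjusted p = 0.114), nor did TAP1, B2M or TNFSF10 (adjusted p = 0.0639, 0.0888 and 0.223). Without siNC replicate 2 alone 33 passed, none of them lower, and without siPRMT6-2 replicate 2 alone 37, and in both cases TNFSF10 did not (adjusted p = 0.0996 and 0.0665). TAP1 did not pass without siNC replicate 3 (adjusted p = 0.0637), nor B2M without siNC replicate 3 or siPRMT6-2 replicate 3 (adjusted p = 0.0959 and 0.0654). NEK5, TIAM1, TOM1L2, DRC3 and SHISA4 each did not pass without siNC replicate 2 or siPRMT6-2 replicate 2 (lowest adjusted p = 0.129, TIAM1).

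**Figure D1:**
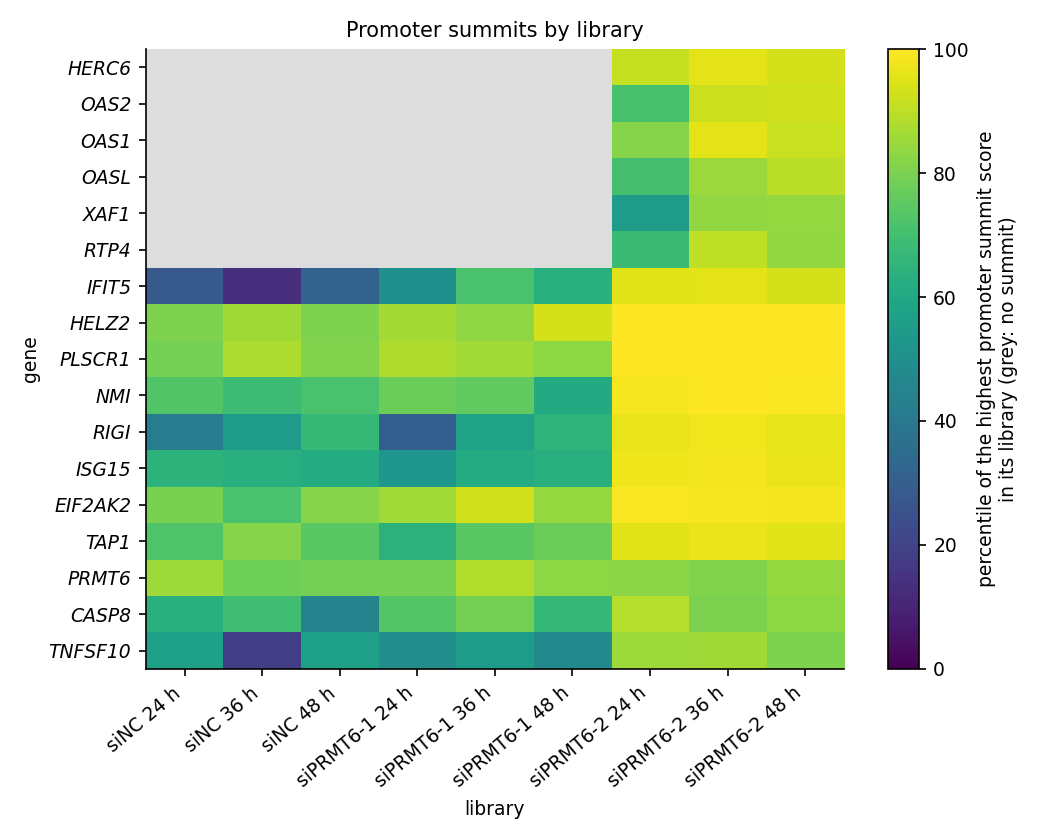
Percentile of the highest promoter summit score within its library (colour, from 0 to 100, grey where no summit was called) for 17 genes (rows) in the 9 libraries (columns). HERC6, OAS2 and OAS1 have summits in the 3 siPRMT6-2 libraries and in no other, whereas PRMT6 stays between 78.1 and 88.6 in all of them.

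In the libraries of the same siRNA, summits were also called at interferon promoters that were not called in the other libraries. In siPRMT6-2, 53, 55 and 54 of the 65 type I interferon promoters were called at 24, 36 and 48 h, against 40, 35 and 37 in siNC and 36, 39 and 36 in siPRMT6-1. For antigen presentation the counts of 37 promoters were 24, 29 and 28 in siPRMT6-2, 21 at every time in siNC, and 22, 24 and 22 in siPRMT6-1. With the siPRMT6-2 label moved within times, both lists had p = 0.037, the smallest the exact permutation test can give, which adjusted to 0.267 over the 18 lists. With the siNC label moved, the test planned for the pooled difference, the exact permutation p was 0.407 and 0.111, and 0 of 18 lists passed. Summits within 25 kb of the type I interferon genes made up 32.1, 38.8 and 37.5 of every 10000 summits in siPRMT6-2, 28.6, 26.8 and 29.8 in siPRMT6-1, and 24.3, 24.0 and 25.8 in siNC. For this measure too 0 of 18 lists passed. After adjustment a list can pass only where most of the 18 reach the smallest p of 0.037. Both counts of 0 were thus nearly fixed beforehand and decide nothing. In leukocyte markers 7, 3 and 5 of 25 promoters were called in siPRMT6-2, against 3, 2 and 2 in siNC and 3, 3 and 4 in siPRMT6-1 (exact permutation p = 0.0741 with the siPRMT6-2 label moved). Of the endothelial and fibroblast markers 2 or 3 of 20 were called in every library.

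**Figure D2:**
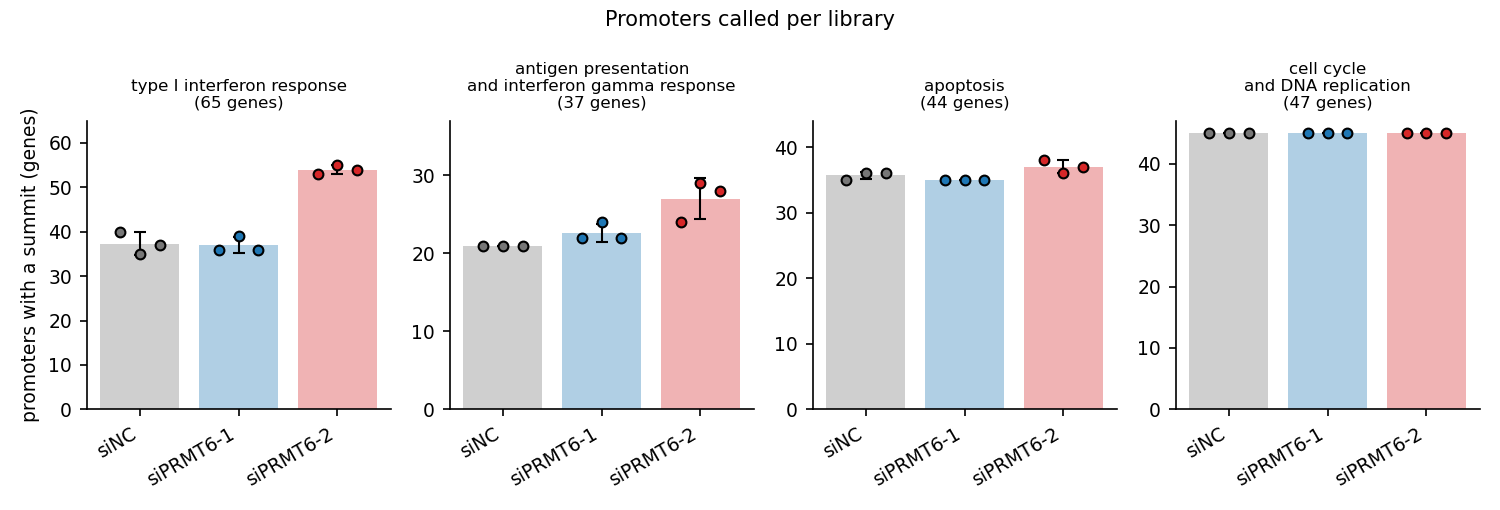
Number of promoters with a summit (vertical axis, genes) for 4 lists, with the top of each axis at the size of the list. Bars are means over 24, 36 and 48 h, error bars SD (n = 3) and points single libraries in that order. For the type I interferon list the siPRMT6-2 libraries reach 53 to 55, above the 35 to 40 of siNC and the 36 to 39 of siPRMT6-1.

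Counts for 1 siRNA alone were added after the data had been seen. There were 29 promoters, at 28 distinct sites, called in all 3 siPRMT6-2 libraries and in none of the other 6. The highest median percentiles were 93.5 for HERC6, on chromosome 4 from 88378852 to 88443097, 92.0 for OAS2 and 91.5 for OAS1, neighbouring oligoadenylate synthetase genes on chromosome 12, 84.8 for OASL and 83.9 for XAF1. RTP4, DHX58, IFI44L and the shared promoter of BST2 and MVB12A followed. Of the 29, 11 were type I interferon genes where 0.132 would fall by chance (Fisher's exact test over 11450 promoters called in at least 3 libraries, adjusted p = 3.21e-18), and 2 were of the nucleic acid sensing list, DHX58 and JAK1 (adjusted p = 0.0188). The JAK1 window was at the upper end of its record, at 65067746 on chromosome 1, with a median percentile of 43.1. Transcript starts inside JAK1 were not examined, so its call may not concern the main promoter of the gene. Genes are not independent replicates in this test. Its background also holds promoters called in all 9 libraries, which could not be called in siPRMT6-2 alone. They made up 9818 of the 11450 but 28 of the 52 type I interferon promoters there. The chance value of 0.132 is therefore too low and the p-value too small. Without the 36 h libraries the count of 29 promoters became 59, without siPRMT6-2 replicate 1 it was 47 and without siPRMT6-2 replicate 3 it was 45. Of distal regions, 271 were called in siPRMT6-2 alone, 1001 without the 36 h libraries, and 590, 626 and 623 without siPRMT6-2 replicate 1, 2 or 3. Fewer libraries make the rule looser by construction, so these rises do not show dependence on particular libraries.

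In siPRMT6-1 no promoter passed against siNC (limma, of 9818 promoters 422 higher and 383 lower at an unadjusted p under 0.05). Without siNC replicate 3, siPRMT6-1 replicate 1 or siPRMT6-2 replicate 3 there were 2, 3 and 2. The smallest p values were those of ODF2 at −1.46 ± 0.23 (SE, adjusted p = 0.0572), HDAC7, a histone deacetylase, at 1.47 ± 0.25 (SE, adjusted p = 0.0894), GDF1 at 1.53 ± 0.27, and IFIT5 with LIPA at 1.26 ± 0.24 (SE, adjusted p = 0.128). The type I interferon list had a median shift of 0.049 and a mean of 0.20, and 1 promoter was higher over the list alone. Its adjusted p was 0.12 with camera and 0.972 with an estimated correlation. It passed camera without siNC replicate 1 (adjusted p = 0.0346), without siPRMT6-1 replicate 1 (adjusted p = 0.0188) and with median-centred log2 scores (adjusted p = 0.00919), whereas its median was −0.034 without siNC replicate 2 (adjusted p = 0.829). The antigen presentation list had a median of 0.13 (adjusted p = 0.223) and the apoptosis list one of −0.035 (adjusted p = 0.971). The promoters called in siPRMT6-1 alone numbered 4, those of TLE1, CCL2, PRR15L and TP53I13, named after their values were seen. For TLE1 and TP53I13 all 9 libraries had a summit within 2.5 kb, so these calls rest on the edge of the window. Leaving out siPRMT6-1 replicate 1, 2 or 3 gave 14, 11 and 14, and leaving out siNC replicate 1 or siPRMT6-2 replicate 1 gave 7 each. A rule over fewer libraries is looser by construction, so such rises do not show dependence on particular libraries.

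The difference between the siRNAs was tested directly. The promoter ranks of 59 genes at 50 sites were higher in siPRMT6-2 than in siPRMT6-1, and those of 20 genes at 19 sites were lower (limma). The genes named here were chosen after their values were seen. The largest differences were those of NMI at 2.74 ± 0.27 (SE, adjusted p = 2.94e-05), RIGI at 2.67 ± 0.27, PLSCR1 at 2.64 ± 0.25, ISG15 at 2.55 ± 0.25 and HELZ2 at 2.45 ± 0.27. The type I interferon list was higher in siPRMT6-2 by a median of 1.43, with 17 of 28 promoters past the threshold and 22 adjusted over the list alone, and the antigen presentation list by 0.86, with 6 of 18 and 10. Both held with an estimated correlation (adjusted p = 0.0107 each). The nucleic acid sensing list was higher by 0.24 with camera's preset correlation, with 2 of 20 and 5 over the list alone, and did not pass with an estimated correlation (adjusted p = 0.11). On the lower side were LYRM1 at −1.69 ± 0.35, HDAC7 at −1.68 ± 0.25, ZNF792 at −1.41 ± 0.27 and OSBP2 at −1.40 ± 0.27. Quantile normalisation of the scores gave 24 higher and 1 lower, and leaving out the 36 h libraries gave 18 higher and 0 lower. The count of 79 was 51 without siNC replicate 1, 44, 35 and 34 without siPRMT6-1 replicate 1, 2 or 3, and 41 and 45 without siPRMT6-2 replicate 2 or 3. LYRM1, ZNF792 and OSBP2 each did not pass without siPRMT6-1 replicate 3 (adjusted p = 0.177, 0.0795 and 0.0558). In the window of 2.5 kb, LYRM1 was at −0.024 (adjusted p = 0.984) and HDAC7 at −0.63 (adjusted p = 0.278), and HDAC7 did not pass without the 36 h libraries either (adjusted p = 0.0794).

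**Figure D3:**
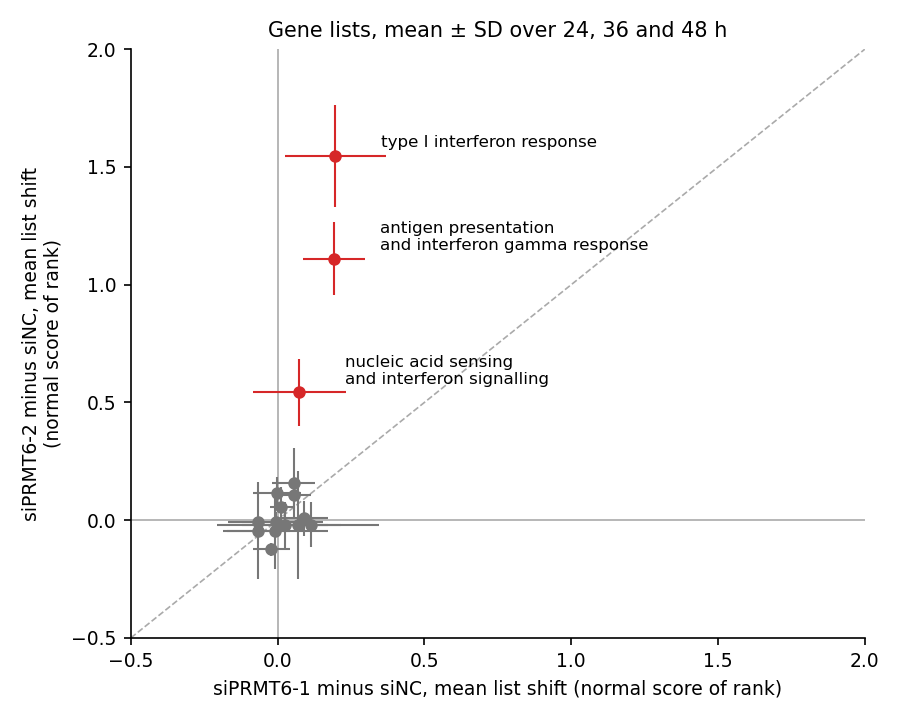
Mean rank shift of each gene list against siNC (normal score units) in siPRMT6-1 (horizontal axis) and siPRMT6-2 (vertical axis), mean ± SD over 24, 36 and 48 h, for the 16 lists tested. The type I interferon list lies at 0.20 and 1.55, far above the dashed line of equal shifts.

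Over the 9818 promoters, the shifts of the siRNAs against the same siNC libraries had a correlation of 0.408 across promoters, which are not independent replicates. This was below the range for unchanged groups simulated against shared controls, which gave 0.500 (0.474 to 0.522 in 100 simulations). The share of promoters with the same sign, 64.1%, was below the simulated range too (mean 66.7%, 65.5 to 68.0), whereas the covariance of 0.0457 was above it (mean 0.0391, 0.0352 to 0.0427). The simulated noise was independent between promoters and between libraries. Real windows share summits and libraries of the same time deviated together, so these ranges may be too narrow, and places outside them decide nothing. Since siPRMT6-1 had 0 calls, an overlap of calls could not be had. The 3 control libraries are too few to divide between the siRNAs.

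The interferon difference was present at the first time sampled. In siPRMT6-2 the mean shift of the type I interferon promoters was 1.47 at 24 h, 1.79 at 36 h and 1.38 at 48 h (mean 1.55 ± 0.22 SD, n = 3), and in siPRMT6-1 it was 0.027, 0.37 and 0.19 (mean 0.20 ± 0.17 SD, n = 3). For antigen presentation the siPRMT6-2 values were 1.07, 1.28 and 0.98. With 1 library per siRNA and time, single times have no replicate check. No promoter passed for a change of the pooled knockdown difference with time (limma, 285 at an unadjusted p under 0.05), and 0 of 16 lists passed, with 1 passing without siPRMT6-1 replicate 1 and 1 without siPRMT6-2 replicate 1. The smallest p values were those of RTL8C at 1.42 ± 0.27 per 12 h and DHCR7 at −1.32 ± 0.27 (adjusted p = 0.8 each).

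Outside the interferon lists, none of the other 13 lists passed camera with either correlation, or fry's test of a shift to 1 side, in any of these 5 comparisons. With summed scores, the mesenchymal list passed camera in siPRMT6-2. Fry's test of change in either direction passed in siPRMT6-2 for the mesenchymal and NF-kB lists (adjusted p = 0.000488 and 0.00743) besides apoptosis. Between the siRNAs it passed for the mesenchymal, Myc target, apoptosis, histone acetylation machinery and endometrial lists (adjusted p = 0.000471, 0.00166, 0.0127, 0.0127 and 0.0242). Their median shifts lay between −0.092 and 0.16 in the pooled comparison (camera, lowest adjusted p = 0.791) and between −0.12 and 0.14 in siPRMT6-2 (camera, lowest adjusted p = 0.314), including p53 targets, the cell cycle, NF-kB genes and stress responses. CCNB1, a mitotic cyclin, had −0.93 ± 0.28 in the pooled comparison (adjusted p = 0.54). The leukocyte list had no promoter called in all libraries, and the endothelial and fibroblast list had 2, so neither was tested by rank.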

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

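The tests of explanations, the counts for 1 siRNA alone and the comparisons with other splits were chosen only after the result was seen. The limma test of single promoters between the siRNAs was planned, and the list tests between them were not.

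The siRNAs against PRMT6 differed from each other in the test of the difference itself, with 79 promoters past the threshold. The median rank shift, siPRMT6-2 minus siPRMT6-1, was 1.43 for the type I interferon list, 0.863 for antigen presentation and 0.236 for nucleic acid sensing, of which the last did not pass with an estimated correlation (adjusted p = 0.11, limma's camera). In the 19 measures with a spread over the 6 knockdown libraries, Dixon's outlier test flagged 0. These libraries pool both siRNAs, so a difference between the siRNAs widens the range and can hide a library that stands apart.

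The pattern weighed was the acetylation of interferon promoters in siPRMT6-2 libraries. Longer or more sensitive lists as the whole cause are argued against, since with all lists at equal length 30 promoters were still called in siPRMT6-2 alone, against at most 11 in any other split. A preparation batch that follows the file codes is argued against too, because the smallest excess of called type I interferon promoters over siNC within the times of 1 shared code was 13, above the range of 5 over the siNC libraries. What stays open is whether siPRMT6-1 acted on the same promoters more weakly or siPRMT6-2 set off a response of its own. Such a response could be one to the RNA itself. PRMT6 loss as the cause would not need a shift in siPRMT6-1 if that siRNA depleted PRMT6 little. The mean shift of these promoters in siPRMT6-1 was 0.196 and did not pass, which does not exclude a small effect, and knockdown strength was not analysed here, so these explanations cannot be told apart.

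Other splits of the same libraries were counted for each comparison. For siPRMT6-2 against the other 6 libraries, 1 of 81 splits that could be fitted with time as a block gave as many as the real 73 promoters, and the highest other gave 1. This siRNA was singled out of 3 after its count was seen, and only 27 of the splits hold 1 library per time, so the share does not settle whether chance can be excluded. For the pooled knockdown the real count was 0, which all 81 splits reach whatever they hold, and the highest other gave 73, in the split that sets siPRMT6-2 apart. For siPRMT6-1 against siNC all 10 splits reach the real 0 in the same way, with 0 as the highest other. For a count of 0 the splits decide nothing. For siPRMT6-2 against siNC and against siPRMT6-1, 1 of 10 splits gave as many as the real 63 and 79, with 1 as the highest other in both, and 10 splits are too few for a share under 0.05.

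For calls, 84 splits were counted. For gained promoters the real 0 is reached by all 84, with 8 as the highest other, which decides nothing either. The lost promoter (1) was matched by 71 splits, with 29 as the highest other. Gained distal regions (19) were matched by 40 splits, with 95 as the highest other, and lost ones (38) by 33, with 271. Chance cannot be excluded for the lost promoter or for the gained and lost distal regions. For siPRMT6-2 alone, 1 split reached the 29 promoters, with 10 as the highest other, and 1 the 271 distal regions, with 142. Libraries of the same time deviated together (correlations of 0.0564 to 0.215), and among the 27 splits with 1 library per time the real split again was the only 1 to reach these counts, with 9 and 90 as the highest other. These shares do not allow for the choice of siPRMT6-2 after the counts were seen either, so they do not settle whether chance can be excluded. For siPRMT6-1 alone, 18 splits reached the 4 promoters and 49 the 27 distal regions, with 29 and 271 as the highest other, so chance cannot be excluded.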

How the results depend on the processing

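The settings with windows at either end of the gene record, with 1 promoter per shared summit and all those for 1 siRNA alone were chosen after seeing the data. The planned window around any annotated transcript start was not run, because transcript coordinates were not used here. The interaction with time has no fit without the time block. Among the main counts and values, 275 alternative values kept their side or size, 115 moved and 5 turned. The cause was not tested, except that leaving out libraries loosens the presence rules by construction. Where this left 1 siRNA with 2 libraries the spread was shared over all groups. Depth is unknown and limits every call.

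The summit difference turned to −1357 without the 36 h libraries, and leaving out single libraries gave −1357 to 2386. Promoters gained numbered 5 with equal list lengths, 5 at a score of at least 5, 15 without 36 h, 2 at 2.5 kb and 17 under the relaxed rule (2 to 12 with a library left out), and promoters lost 13 without 36 h, 2 at 2.5 kb and 7 relaxed (2 to 8). Distal regions gained numbered 124 without 36 h and 112 relaxed (26 to 114), and lost 495 and 190 (49 to 261). For promoters called in siPRMT6-1 alone, equal lengths gave 8, the score limit 1 and no 36 h libraries 16 (4 to 14), and for promoters uncalled in siPRMT6-1 alone 5, 5 and 48, with 0 at 2.5 kb (1 to 23). Promoters called in siPRMT6-2 alone numbered 59 without 36 h (30 to 47) and 27 to 33 under the other settings. Promoters uncalled in siPRMT6-2 alone numbered 3, with 6 at equal lengths and 14 without 36 h (3 to 18). Distal regions called in siPRMT6-1 alone numbered 48 at equal lengths and 154 without 36 h (35 to 229), and in siPRMT6-2 alone 1001 without 36 h (298 to 626).

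Rank shifts of the pooled knockdown gave 2 promoters with summed scores and 0 under every other setting. siPRMT6-1 gave 4 with summed scores and 1 at a score of at least 5 (0 to 3 with a library left out). siPRMT6-2 gave 35 with median-centred log2 scores, 28 with quantile normalisation and 21 without 36 h (33 to 67), and 34, 28 and 21 of these were among the 63. The difference between the siRNAs gave 28, 25 and 18 under these settings, 36 with summed scores and 52 without the time block (34 to 65). The fit without the time block gave 47 for siPRMT6-2. Lists past the threshold in the pooled comparison numbered 0 with an estimated correlation and 0 with fry, against 3 (2 to 3). In siPRMT6-1 they numbered 1 with median-centred log2 scores (0 to 1), and for the change with time 0 to 1 with a library left out. The median of the type I interferon list in siPRMT6-1 was −0.034 to 0.15 with a library left out. In siPRMT6-2 the medians of the 3 interferon lists stayed above 0, between 1.51 and 1.86 for type I interferon, and passed camera with the preset correlation under all settings. Nucleic acid sensing did not pass with an estimated one (adjusted p = 0.0511), and with summed scores 4 lists passed. For named genes and interferon lists, 1181 alternative values kept their side of the threshold and direction, 140 no longer passed, 9 newly passed and 1 turned. SFN, NEK5, TIAM1 and SHISA4 in siPRMT6-2 and LYRM1 between the siRNAs were among those most often lost.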

Other observations

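The regions and promoters below were chosen after their values were seen, as was the test of distal ranks.

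More than 2.5 kb from the window centres used here, the regions called in siPRMT6-2 alone with the highest scores lay near genes of several kinds. Transcript starts inside a gene were not known here, so a region within a gene, such as that in IFI27 below, may be a promoter. The region on chromosome 22 from 17243636 to 17244178, nearest to ADA2, an adenosine deaminase, had a median percentile of 87.0. That on chromosome 18 from 62506470 to 62507054, nearest to ZCCHC2, had 85.7. Regions within IFI27 (chromosome 14, 94110674 to 94111220), near LY6E (chromosome 8, 143024178 to 143024993) and within RNF213 (chromosome 17, 80263542 to 80264560) had 82.7, 81.2 and 79.2. IFI27, LY6E and RNF213 are known interferon-stimulated genes. Of the 271 regions, 4 lay within 25 kb of a type I interferon gene where 0.418 would fall by chance (Fisher's exact test, adjusted p = 0.0142). The background of 24610 regions holds those called in all libraries, which could not be in this set, so the chance value may be off. Among the 9242 distal regions called in all libraries, no rank shift passed (limma, siPRMT6-2 against siNC, 1098 at an unadjusted p under 0.05, smallest adjusted p = 0.0734).

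Among the 29 promoters called in siPRMT6-2 alone, 14 were in the interferon lists. The others included BATF2, SLC15A3 and MVP with median percentiles of 75.8, 68.7 and 50.6, and SERPING1 and RAET1E with 9.41 and 2.23. Within 2.5 kb, 6 libraries had a summit for BATF2 and all 9 for MVP, so these calls rest on the edge of the window. Of the 58 promoters higher in siPRMT6-2 than in siNC, 31 were outside the interferon lists. Some of the 31, such as LIPA and APOF, share windows with the list members IFIT5 and STAT2. The lists do not hold every interferon-stimulated gene, so 31 is not a count of promoters unrelated to interferon. Others of the 31 were PML (window shared with STOML1), TRIM56, TRIM38, OGFR and FN1. FN1, which encodes fibronectin, was at 1.25 ± 0.24 (SE, adjusted p = 0.0167, limma). SFN and OSBPL7 passed at 1.08 ± 0.24 and 1.38 ± 0.27 (SE, adjusted p = 0.0445 and 0.0167). SFN was at 0.28 in the window of 2.5 kb (adjusted p = 0.817) and OSBPL7 at 0.73 with summed scores (adjusted p = 0.565). The calls of SFN, OSBPL7 and FN1 were each lost without siNC replicate 1 (adjusted p = 0.147, 0.135 and 0.117).

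The 11 type I interferon promoters called in siPRMT6-2 alone had a median percentile of 70.5 at 24 h, 83.9 at 36 h and 84.4 at 48 h. With 1 library per time this has no replicate check.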
